A study of Mus musculus with 6 samples.

How the data were processed

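Spinal cord cells of healthy mice and of mice at EAE onset were stained with DCFDA at 10 µM and sorted on CD11b and dye fluorescence, and 1 droplet library of transcript 3' ends was made per sample, per the labels' protocols. The authors deposited UMI counts per gene and cell barcode for each of 6 libraries, and per the file headers these are whole-number matrices. Cell Ranger 2.0.1, Seurat 3 and R 3.4.2 are named with the mm10 build in the submitters' processing notes, without the role of each; the aligner's settings, the annotation and the cell calling settings are not given in the sources used here. The files held 9079 barcodes, 378 more than the 8701 cells that the design text states, and the filter that gives the stated number is not given in the sources used here. Each file listed 38293 gene IDs, of which 36345 were in the reference name table; 293 symbols belonged to more than 1 ID, so genes were matched by ID.

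Cells with at least 200 genes and at most 10% mitochondrial UMIs were kept, which removed 1 barcode and left 9078. Library totals ran from 915197 to 23407825 UMIs, 71869176 in all. Intervals and limits on shares cover counting error only. Between the 2 libraries of a group, chi-square per degree of freedom of counts over genes ran from 6.73 to 74.6 in all cells and from 3.00 to 5.99 in microglia-like cells, so replicates differed by more than counting error.

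Counts were scaled to 10000 per cell and log-transformed with scanpy 1.11.5 (anndata 0.12.19, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, Python 3.11.15). From 2000 variable genes, 30 principal components and 15 exact nearest neighbours were computed over all libraries together, without integration. Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) at resolution 1 with seed 7 gave 21 clusters. Clusters were named from marker lists of 13 cell classes, fixed before the data were examined. A marker counted at 0.5 per 10000 UMIs or more; a cluster took the class with the highest relative marker level, which needed 3 markers and a level of 0.25. Only a cluster with microglia at a relative level of 0.1 or more and monocyte/macrophage or endothelial markers at 0.1 or more was called mixed, so other named clusters can hold further markers; the T cell-like cluster was highest for natural killer cell markers as well. These naming thresholds were set after the clusters were seen. Names end in -like because they rest on RNA alone. Of 338 list and marker genes 337 were in the files, the exception being Ighd. Scrublet, run per library, called 29 cells (0.319%), only 2 of them among the cells with both microglial and monocyte/macrophage genes, so its calls were not removed.

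UMI counts were summed per library over all cells, or over a class with at least 20 cells in the library. Sums were compared with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr with a minimum count of 10, quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05), with limma 3.58.1 for gene lists. CPM given beside tests are over TMM-scaled totals, and those of the figure of gene levels and of the closing parts are over plain totals. Standard errors are the absolute log2 fold change over the square root of F. All 3 groups shared 1 fit for all cells and for microglia-like cells, which left 3 residual degrees of freedom; the fit for monocyte/macrophage-like cells used the 4 EAE libraries and left 2. The test of whether the gate difference differed by class used 8 sums with the library as a block and left 2. Common biological coefficients of variation were 0.221 in all cells, 0.172 in microglia-like cells, 0.201 in monocyte/macrophage-like cells and 0.130 in the fit over both classes. Figures were drawn with matplotlib 3.10.9.

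The 17 gene lists were fixed before the data were examined, as were the tests, the markers, the rule for named genes and the alternatives, except those said in the closing parts to be chosen later. Lists were NADPH oxidase, glutathione metabolism, ROS scavenging, coagulation and fibrinolysis, class II and class I antigen presentation, interferon response, inflammatory cytokines and enzymes, chemokines, glycolysis, oxidative phosphorylation, homeostatic microglia, disease-associated microglia, lysosome and phagocytosis, complement, cell cycle and dissociation stress. They were tested with camera at a preset correlation of 0.01, and again with a correlation estimated per list. No list call at the preset correlation held with the estimated one, in any comparison. The estimated form also uses only the few residual degrees of freedom of a fit, so this does not rest on the correlation alone. Values of 2 single genes are not reported here; they stay in the counts of genes.

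Named genes were up to 6 per direction with the largest absolute log2 fold change among genes with adjusted p under 0.05, an average log2 CPM of at least 5 and both libraries of 1 group above both of the other. To these were added up to 4 members of each list with the smallest p, and a fixed set: Cybb, Ncf1, Cyba, Ggt1, Il1b, Tnf, Nos2, Arg1, Cd74, Tmem119, P2ry12, Ccr2, Ly6c2, F10, Apoe and Spp1. Predicted, ribosomal, mitochondrial, immunoglobulin, T cell receptor and sex-linked genes were left out. Ggt1 had at most 2 UMIs in a library and passed no count filter, so no fold is given. Against a group without counts a fold is a lower bound from a floor of 3 counts over the group, and against 1 to 3 counts it is a ratio with a 95% counting interval. Coordinates are those of GENCODE M21 on GRCm38 (mm10).

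The test scripts were tested on simulated data with the real library sizes, in which 100 genes changed 2-fold and 100 changed 4-fold. Each gene otherwise had its mean over all libraries of the fit, and its spread followed the trended dispersion of that fit. Gene-specific spread and correlation between same-numbered libraries were left out. Recovery and false calls therefore hold for that model and can differ in the real data. Recovery of 2-fold and 4-fold changes was 21% and 80% for EAE ROS+ against ROS- in all cells, 21% and 71% for EAE ROS- against healthy, and 23% and 74% for EAE ROS+ against healthy. In microglia-like cells it was 12% and 70% between the EAE gates and 36% and 96% between EAE ROS- and healthy. It was 34% and 89% in monocyte/macrophage-like cells and 9% and 42% for differences between the classes. False calls were 4 of 105, 5 of 97, 6 of 103, 3 of 85, 0 of 132, 5 of 128 and 3 of 54 in the same order.

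Alternatives were size factors of the DESeq2 type, DESeq2 1.42.0, no low count filter, at least 500 genes and at most 5% mitochondrial UMIs per cell, no cell filter, removal of Scrublet calls, class by marker sums, resolutions 0.5 and 2, a replicate block, only the 2 groups compared, each library left out, and gene lists restricted to an average log2 CPM of at least 5. Phase calls, trajectories and pathways beyond the 17 lists were not analysed here.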

Results

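The series measured RNA in single cells from the mouse spinal cord that carried the myeloid surface protein CD11b. Live cells had been stained with DCFDA, a dye that turns fluorescent when reactive oxygen species (ROS) oxidise it, and were sorted as ROS+ or ROS-. The C57BL/6 mice were 10 weeks old and were either healthy or at the onset of experimental autoimmune encephalomyelitis (EAE), a model of multiple sclerosis started by immunisation with a myelin peptide. There were 6 libraries in 3 groups of 2: EAE ROS+, EAE ROS- and healthy ROS-. The EAE ROS+ libraries held 1745 and 2233 barcodes with 23407825 and 15450857 UMIs. The EAE ROS- libraries held 1614 and 1530 barcodes with 15754177 and 11909166 UMIs, and the healthy libraries held 1755 and 202 barcodes with 4431954 and 915197 UMIs. Median UMIs per cell were 9543 and 5467 in EAE ROS+, 7483.5 and 6427 in EAE ROS-, and 2178 and 3617.5 in healthy libraries. The labels do not say that libraries of a group came from separate animals, so each p-value below measures only the spread between samples.

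Monocyte/macrophage-like cells made up nearly all of the EAE ROS+ libraries, and microglia-like cells made up nearly all of the larger healthy library. Cells marked by Ccr2, Ly6c2 and other monocyte and macrophage genes were 93.4% (exact Clopper-Pearson 95% interval 92.1% to 94.5%) and 96.5% (95.6% to 97.2%) of the EAE ROS+ libraries. They were 39.5% (37.1% to 42.0%) and 64.6% (62.2% to 67.0%) of the EAE ROS- libraries. None was found among 1755 and 202 healthy cells, which allows shares of up to 0.210% and 1.81% by the same interval. Microglia-like cells, marked by Tmem119, P2ry12 and Sall1, were 1.60% (1.07% to 2.31%) and 0.985% (0.618% to 1.49%) of EAE ROS+ cells. They were 29.0% (26.8% to 31.3%) and 15.9% (14.1% to 17.8%) of EAE ROS- cells, and 99.5% (99.0% to 99.8%) and 35.1% (28.6% to 42.2%) of healthy cells. The remaining 131 cells of healthy replicate 2 carried endothelial genes beside microglial ones.

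The share of monocyte/macrophage-like cells averaged 94.9% ± 2.16 (SD, n = 2) in EAE ROS+ and 52.1% ± 17.7 (n = 2) in EAE ROS- libraries, a difference of 42.9 percentage points. The share of microglia-like cells averaged 1.29% ± 0.438 in EAE ROS+, 22.4% ± 9.27 in EAE ROS- and 67.3% ± 45.5 in healthy libraries. Dendritic cell-like cells, with Ccl17, Ccl22 and Ccr7, averaged 10.0% ± 2.99 of EAE ROS- cells and 0.182% ± 0.0671 of EAE ROS+ cells. T cell-like cells, with Cd3g and Ifng and the natural killer cell markers Nkg7 and Gzma, averaged 2.29% of EAE ROS- cells and 0.0958% ± 0.0545 of EAE ROS+ cells. Neutrophil-like cells were seen only in the EAE ROS+ libraries, as 9 and 13 cells (0.516% and 0.582%). A count of 0 in the EAE ROS- libraries allows up to 0.228% and 0.241% by the exact 95% interval. Both libraries of each group lay on the same side of both libraries of the other for these classes between the EAE gates. The exact two-sided permutation test of 2 against 2 libraries cannot give a p below 0.33, which it gave here.

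**Figure D1:**
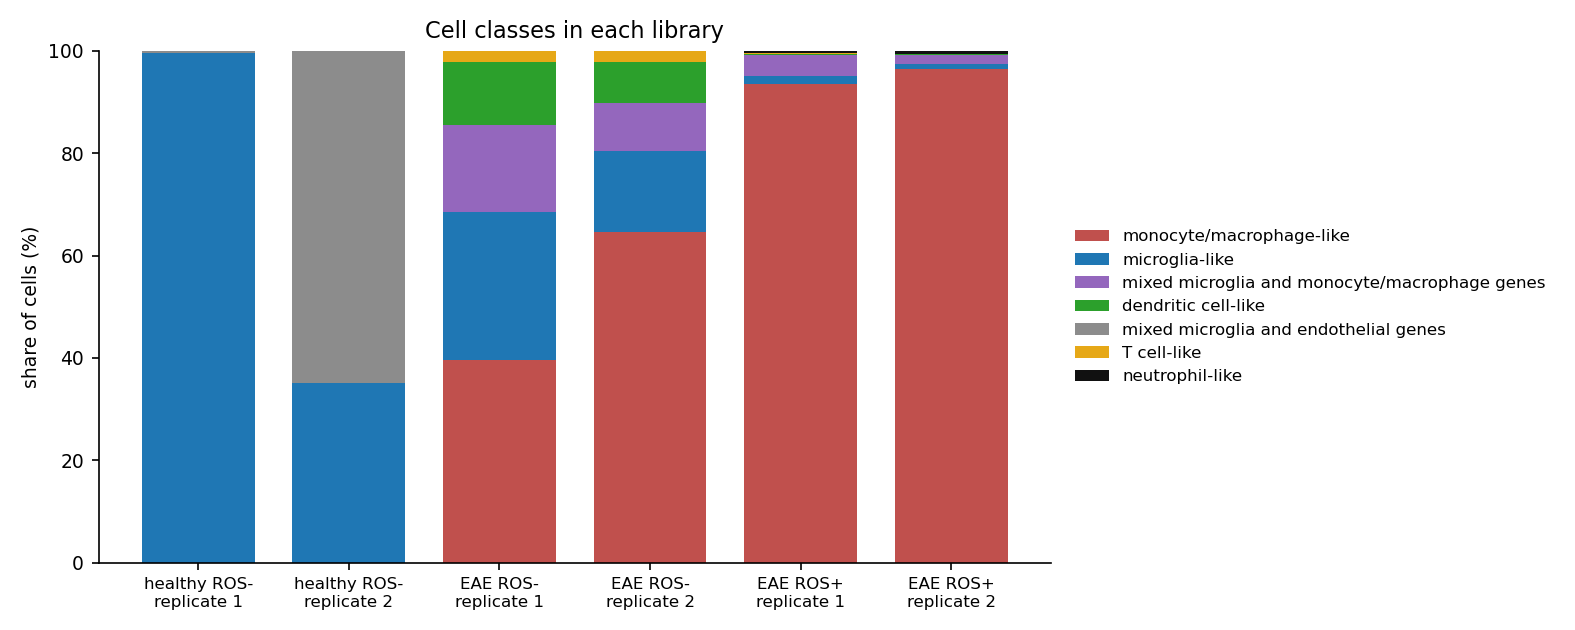
Share of cells (%) of each class in each of the 6 libraries, as stacked bars. Monocyte/macrophage-like cells fill 93.4% and 96.5% of the EAE ROS+ bars, and cells with endothelial genes fill 64.9% of the bar of healthy replicate 2.

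The comparison of all sorted EAE cells asked which genes set ROS+ apart from ROS- libraries at disease onset; these differ in cell classes, so a change here can reflect the shares of microglia-like, dendritic cell-like and other cells. Of 13631 genes tested, 17 rose, among them S100a9, Camp and Thbs1, and 278 fell, among them Slc2a5, P2ry12 and Ccl17 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The counts were 78 up and 518 down with a replicate block, 651 and 1188 with a block over the EAE libraries only, and 219 and 787 with no low count filter. S100a9, a calcium-binding alarmin of neutrophils, stood at 211 and 517 CPM (counts scaled to a common library total) in ROS+ and at 0.467 and 0.648 in ROS- libraries (adjusted p = 0.000257). Camp and Ngp, which encode neutrophil granule proteins, rose as well. Ngp had 3159 counts against 2, a ratio of 1124 (95% counting interval 311 to 9288). S100a9, Ngp, Camp and S100a8 were among the leading genes of the 22 neutrophil-like cells, 9 and 13 in the EAE ROS+ libraries. These rises can therefore rest on few cells, a spread that the counting interval does not cover. Saa3, an acute-phase protein, rose 3.37-fold (log2 1.75 ± 0.25 SE, adjusted p = 0.00928), from 627 ± 11.1 to 2111 ± 568 CPM (SD, n = 2). S100a8, the partner of S100a9, rose 9.85-fold (log2 3.30 ± 0.51, adjusted p = 0.0119). Thbs1, an adhesive glycoprotein of platelets and monocytes, rose 3.25-fold (1.70 ± 0.29, adjusted p = 0.0177) and F13a1, which crosslinks fibrin, 3.29-fold (1.72 ± 0.29, adjusted p = 0.018).

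Fscn1, an actin-bundling gene of mature dendritic cells that microglia also express, fell most surely among the lower genes, with log2 -4.33 ± 0.30 (adjusted p = 0.000573). Microglial identity genes fell with it: the fructose transporter Slc2a5 (-2.93 ± 0.26, adjusted p = 0.00192), the adhesion receptor Gpr56 (-3.35 ± 0.31, adjusted p = 0.00192) and the transcription factor Sall1 (-2.98 ± 0.36, adjusted p = 0.00411). The purinergic receptor P2ry12 was at 27.3 ± 0.850 CPM in ROS+ and 127 ± 45.8 CPM in ROS- libraries (log2 -2.21 ± 0.29, adjusted p = 0.00534). Siglech (-3.29 ± 0.44) and Tmem119 (-2.21 ± 0.29) fell with adjusted p = 0.00624. The chemokine Ccl12 (-2.31 ± 0.33, adjusted p = 0.00837) and the immune checkpoint gene Lag3 (-3.63 ± 0.54, adjusted p = 0.0101) fell, as did Ccl17, a dendritic cell chemokine that attracts T cells (-4.37 ± 0.88, adjusted p = 0.0392). Il12b, the shared subunit of interleukins 12 and 23, fell too (-2.86 ± 0.51, adjusted p = 0.0295). Each of these genes was lower in both ROS+ than in both ROS- libraries.

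Of 15 homeostatic microglia genes, 9 fell and 6 were not called (13 fell adjusted over the list alone). Their median log2 change was -2.07 (camera adjusted p = 9.11e-26 with a preset correlation, adjusted p = 0.248 with an estimated correlation). Of 17 cell cycle genes, 5 fell, among them Ccnb2 (-2.15 ± 0.33, adjusted p = 0.0114), Stmn1, Rrm2 and Mcm5, and 15 fell adjusted over the list alone. The cell cycle median was -1.56 (adjusted p = 1.16e-17; adjusted p = 0.248 with an estimated correlation), while in microglia-like cells alone it was 1.05. With a replicate block 11 homeostatic and 14 cell cycle genes fell, and with a block over the EAE libraries only 13 and 15. In the coagulation and fibrinolysis list, Thbs1 and F13a1 rose and Tfpi, an inhibitor of the clotting start, fell by 2.03 on the log2 scale (3 up and 1 down adjusted over the list alone; 2 up and 1 down with a replicate block, 9 up and 1 down with a block over the EAE libraries only). Its median was 0.83 (adjusted p = 0.00203; adjusted p = 0.565 with an estimated correlation), and F10, the clotting protease, was at 601 ± 56.2 against 399 ± 236 CPM (adjusted p = 0.589).

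Cybb, the catalytic subunit of the phagocyte NADPH oxidase, averaged 975 ± 133 CPM in ROS+ and 676 ± 63.5 in ROS- libraries (log2 0.53 ± 0.23, adjusted p = 0.395, not called). Its partners Ncf1 (0.06, adjusted p = 0.938) and Cyba (0.34, adjusted p = 0.658) were not called either, and 0 of 7 NADPH oxidase genes were, with none adjusted over the list alone. The list median was 0.34 (adjusted p = 0.0588). None of the 15 glutathione metabolism genes was called over all genes, with 3 up and 1 down adjusted over the list alone. The values were 1.21 ± 0.37 for the glutathione transferase Mgst1 and 2.46 ± 0.62 for Mgst2 (adjusted p = 0.165 and 0.0869). The glutathione median was 0.48 (adjusted p = 0.00282; adjusted p = 0.248 with an estimated correlation). ROS scavenging genes had a median of 0.36 with 0 of 14 called (adjusted p = 0.00533; adjusted p = 0.658 with an estimated correlation). These counts depend on the replicate block: with one, 3 glutathione genes were called up, and with one over the EAE libraries only 6 glutathione genes were called up and 1 down, and 2 NADPH oxidase and 2 ROS scavenging genes up.

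Glycolysis (median 0.39, adjusted p = 0.00437) and oxidative phosphorylation (0.30, adjusted p = 0.00211) lists had higher medians with no gene called, and both had adjusted p = 0.658 with an estimated correlation. The interferon response median was 0.47 (adjusted p = 0.035; adjusted p = 0.703 with an estimated correlation), and that of the dissociation stress list, with Fos and Nr4a1, was 0.53 (adjusted p = 7.21e-05; adjusted p = 0.621 with an estimated correlation). Class II (median -0.03, adjusted p = 0.929, test direction up) and class I (0.01, adjusted p = 0.612) antigen presentation lists had no called gene, and Cd74 stood at 0.03 (adjusted p = 0.989). The inflammatory list (0.52, adjusted p = 0.172) held 1 called gene, Il12b, while Il1b was at 0.50 ± 0.37, Tnf at -0.17 ± 0.23, Nos2 at -0.02 ± 0.53 and Arg1 at 0.94 ± 0.56. Chemokines had a median of 0.18, a mean of -0.28 and a downward test (adjusted p = 0.408), with Ccl12 called and 4 lower adjusted over the list alone. Disease-associated microglia genes (median -0.15, adjusted p = 0.544; Apoe 1.03 ± 0.48), lysosome genes (-0.11, adjusted p = 0.234) and complement genes (-0.46, adjusted p = 0.453; C1qa -1.70 ± 0.55) had no called gene. Adjusted over the list alone, 1 disease-associated gene was higher and 5 lower, 2 lysosome genes were lower, 2 complement genes were higher and 4 lower, and the other lists of this paragraph had the same counts. With a replicate block, 2 disease-associated, 1 lysosome and 2 complement genes were called lower; with one over the EAE libraries only, 4 disease-associated genes were higher and 7 lower, 4 lysosome genes lower, 2 complement genes higher and 5 lower, 4 chemokines higher and 6 lower, 3 inflammatory genes higher and 1 lower, and 8 dissociation stress, 2 glycolysis and 1 interferon response genes higher.

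**Figure D2:**
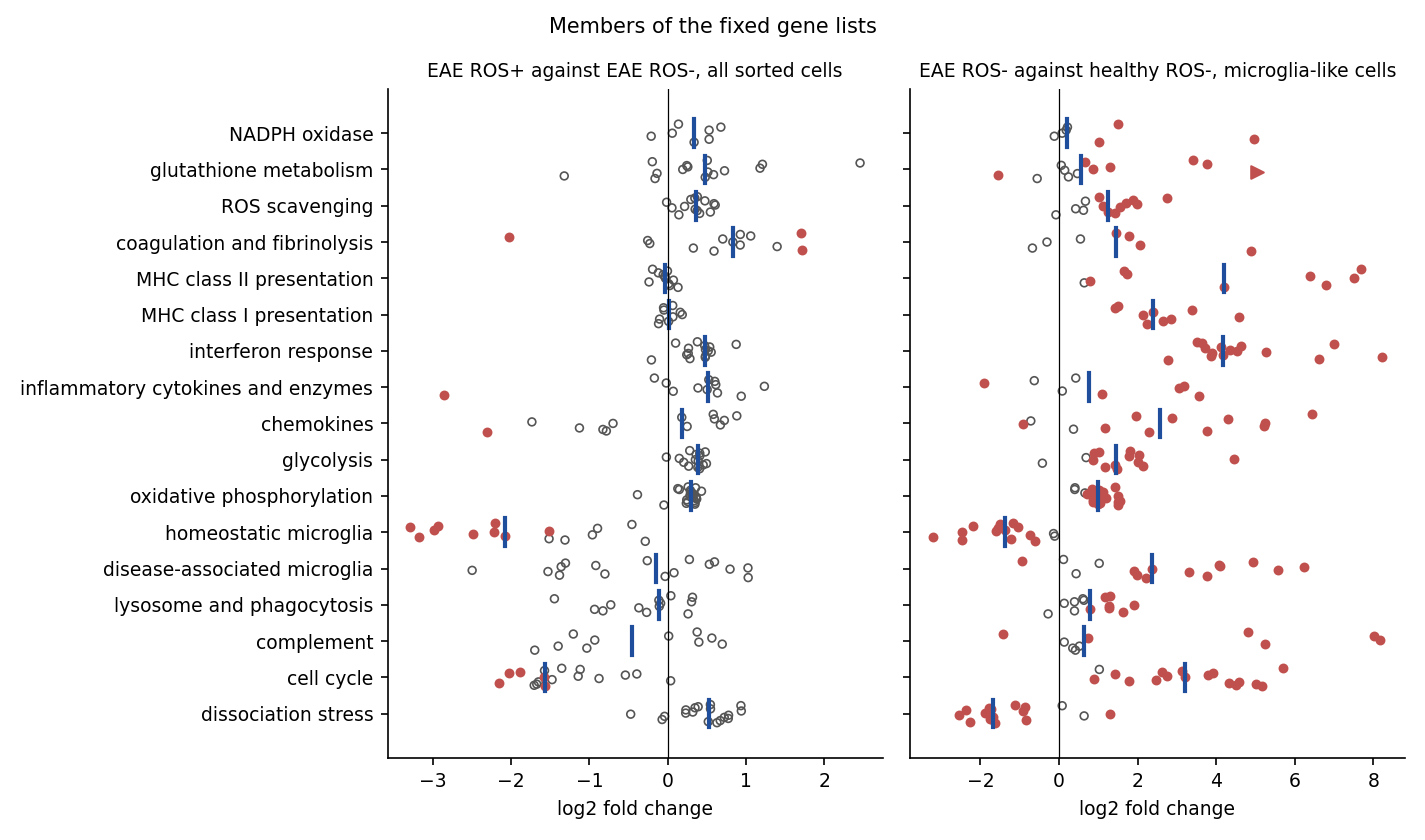
log2 fold change of each member of the 17 gene lists, for EAE ROS+ against EAE ROS- in all sorted cells (left) and EAE ROS- against healthy ROS- in microglia-like cells (right); filled red points had adjusted p under 0.05, open points did not, the triangle is the lower bound of Gpx3, which had no counts in healthy cells, and blue bars are medians. The homeostatic microglia median is -2.07 on the left and -1.37 on the right, and the interferon response median is 0.47 and 4.18.

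The 295 calls in all EAE cells became 133, 182, 632, 123, 146 and 152 without EAE ROS- replicate 1, EAE ROS+ replicate 1, EAE ROS- replicate 2, EAE ROS+ replicate 2, healthy replicate 1 and healthy replicate 2. The calls of S100a8, Lag3, Tfpi, Stmn1, F13a1, Rrm2, Il12b and Ccl17 ended without either healthy library (adjusted p from 0.0543 to 0.128). Without EAE ROS- replicate 1 those of Ccnb2, F13a1, Il12b, Mcm5, Rrm2, Tfpi and Thbs1 ended (0.0544 to 0.36), without EAE ROS+ replicate 1 those of Ccl17, Il12b, Mcm5 and Thbs1 (0.0636 to 0.138), and without EAE ROS+ replicate 2 those of Ccl12, Ccnb2, F13a1, Il12b, Mcm5, Rrm2, Stmn1 and Tfpi (0.0577 to 0.16). DESeq2 did not call Ccl17 (0.0953). The log2 value of Ccl17 was -5.12, -3.54, -2.76 and -6.16 without EAE ROS- replicate 1, EAE ROS+ replicate 1, EAE ROS- replicate 2 and EAE ROS+ replicate 2. Without EAE ROS- replicate 1, Lag3 was at -2.69, Siglech at -2.53 and Il12b at -2.22; Lag3 was at -4.47 without EAE ROS+ replicate 1, and S100a8 at 4.23 without EAE ROS- replicate 2 and 2.67 without EAE ROS+ replicate 2. S100a9, Camp and Ngp stayed called without EAE ROS+ replicate 2, with folds over 1.5 times smaller, and those of Camp and Ngp were over 1.5 times larger without EAE ROS+ replicate 1.

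Within microglia-like cells, edgeR called 6 genes higher in the EAE ROS+ than in the ROS- gate. Fosb, an AP-1 transcription factor, rose 3.39-fold (log2 1.76 ± 0.31), at 271 and 281 CPM against 91.1 and 69.5. Ube2c (3.30-fold, 1.72 ± 0.31) and Ube2s (2.54-fold, 1.34 ± 0.24), which tag mitotic proteins for destruction, and Nucks1 (2.69-fold, 1.43 ± 0.26), a chromatin protein of dividing cells, rose as well. All 4 had adjusted p = 0.0394 and were higher in both ROS+ than in both ROS- libraries. The remaining 2 of 6 calls, named here after their values were seen, were the nuclear import gene Kpna2 (1.84 ± 0.34) and S100a8 (3.75 ± 0.61). Of 8073 genes tested, edgeR called 0 lower, with 530 of all genes at an unadjusted p under 0.05, and DESeq2 called 7 higher and 0 lower; edgeR called 16 higher and 0 lower with a replicate block, and 55 higher and 19 lower with a block over the EAE libraries only. The cell cycle list had a median of 1.05 with 1 gene called and 10 of 17 adjusted over the list alone (camera adjusted p = 9.9e-17, and 0.34 with an estimated correlation). A cluster marked by Top2a and Ube2c held 18 of 28 microglia-like cells of EAE ROS+ replicate 1 and 6 of 22 of replicate 2. In the EAE ROS- libraries it held 18.4% and 26.3%, so the excess of such cells was in EAE ROS+ replicate 1. Mki67 (1.56 ± 0.34, adjusted p = 0.0937) and Birc5 (1.54 ± 0.31, adjusted p = 0.0771) were not called. The dissociation stress list had a median of 0.91 with 1 called and 13 of 17 adjusted over the list alone (adjusted p = 3.15e-26; adjusted p = 0.145 with an estimated correlation). With a replicate block 3 cell cycle and 4 dissociation stress genes were called higher, and with a block over the EAE libraries only 4 and 10. Egr1 (1.37 ± 0.27, adjusted p = 0.0677), Atf3 (1.32 ± 0.27, adjusted p = 0.0771) and Fos (1.13 ± 0.23, adjusted p = 0.0791) missed the threshold.

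Oxidase genes in ROS+ microglia-like cells were not called: Cybb was at 0.53 ± 0.37, Ncf1 at -0.06 ± 0.26 and Cyba at -0.11 ± 0.25 (adjusted p from 0.793 to 0.987). Il1b (0.14 ± 0.23), Tnf (0.92 ± 0.33), Cd74 (-0.21 ± 0.30) and Apoe (-0.22 ± 0.33) were not called, and P2ry12 was at -0.75 ± 0.24 (adjusted p = 0.482). Homeostatic genes had a median of -0.43 (adjusted p = 3.69e-05; adjusted p = 0.34 with an estimated correlation) and lysosome genes, with Ctsl at -0.74 ± 0.24, one of -0.48 (adjusted p = 6.07e-06; adjusted p = 0.378 with an estimated correlation). Chemokines had a median of 0.22 (adjusted p = 0.0209; adjusted p = 0.378 with an estimated correlation), with 3 up adjusted over the list alone. Coagulation (0.33, adjusted p = 0.0312; adjusted p = 0.378 with an estimated correlation) and oxidative phosphorylation (0.19, adjusted p = 0.0079; adjusted p = 0.34 with an estimated correlation) had positive medians. Interferon response (-0.25, adjusted p = 0.0312; adjusted p = 0.364 with an estimated correlation), class I presentation (-0.29, adjusted p = 0.0401; adjusted p = 0.34 with an estimated correlation) and complement (-0.26, adjusted p = 0.0401; adjusted p = 0.368 with an estimated correlation) had negative ones. The other lists had adjusted p from 0.118 to 0.552. Among them, glutathione metabolism had a median of -0.13 and an upward test, and inflammatory genes a median of 0.05, or 0.33 with genes absent from 1 group at their bound, and a mean of -0.51. Adjusted over the list alone, 1 coagulation and 2 glutathione genes were higher, and the remaining lists of this paragraph had no call. With a replicate block no gene of these lists was called over all genes; with a block over the EAE libraries only, 5 lysosome, 2 homeostatic, 2 class I, 1 class II and 1 disease-associated genes were called lower and 2 chemokines and 1 glutathione gene higher.

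The ROS+ sums rest on 28 and 22 microglia-like cells with 295618 and 140340 UMIs, and none of the 4 genes named by rule kept its call under every alternative. Without EAE ROS+ replicate 1, Ube2c was at 1.10 (adjusted p = 0.854) and Nucks1 at 1.16 (adjusted p = 0.808). Counts of calls were 3, 2, 26, 16, 0 and 21 without EAE ROS- replicate 1, EAE ROS+ replicate 1, EAE ROS- replicate 2, EAE ROS+ replicate 2, healthy replicate 1 and healthy replicate 2.

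In monocyte/macrophage-like cells, edgeR called none of 11735 genes between the EAE ROS+ and ROS- gates, with 369 at an unadjusted p under 0.05; with a replicate block it called 21 up and 28 down, and DESeq2 without one called 3 up and 5 down. Cybb was at 899 and 743 CPM in ROS+ against 815 and 793 in ROS- cells (log2 0.03 ± 0.20). Ncf1 (0.10 ± 0.17), Cyba (0.03 ± 0.23), Il1b (-0.11 ± 0.29), Tnf (-0.06 ± 0.16) and F10 (-0.10 ± 0.27) were also near 0. Thbs1 (1.09 ± 0.18) and F13a1 (1.04 ± 0.19) of the coagulation list had the smallest p-values among the genes of the lists and were 2 of 13 up adjusted over the list alone. Values were 1.10 ± 0.27 for the plasma glutathione peroxidase Gpx3, 1.84 ± 0.50 for Mgst2, 0.32 ± 0.38 for Arg1 and -0.67 ± 0.46 for Nos2. Class II genes had a median of -0.33, with H2-Ab1 at -0.54 ± 0.38 and Cd74 at -0.43 ± 0.39 (adjusted p = 0.014; adjusted p = 0.8 with an estimated correlation). Lists of glutathione metabolism (0.15, adjusted p = 0.00596), coagulation (0.23, adjusted p = 0.00664) and dissociation stress (0.18, adjusted p = 0.00308) had positive medians, and that of the cell cycle (-0.40, adjusted p = 0.000285) a negative one, each with adjusted p = 0.8 with an estimated correlation. Homeostatic genes had a median of -0.27 (adjusted p = 0.0121; adjusted p = 0.994 with an estimated correlation). The other lists had adjusted p from 0.0876 to 0.991; inflammatory, complement and disease-associated lists had medians, means or tests of different sign, all within 0.08 of 0. With a replicate block 2 coagulation genes and 1 dissociation stress gene were called higher, and 2 homeostatic, 2 disease-associated and 1 complement genes lower. Without EAE ROS+ replicate 1 there were 50 calls and without EAE ROS+ replicate 2 there were 27.

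The next comparison asked whether the gate difference itself differed between microglia-like and monocyte/macrophage-like cells, with the library as a block. Mitotic genes were among those that did: the log2 values of Birc5, Kpna2, Mki67 and Ube2c were 1.54, 1.84, 1.56 and 1.72 in microglia-like cells and -1.02, -0.52, -0.40 and -0.38 in monocyte/macrophage-like cells. The differences between the classes were 2.39 ± 0.42 for Birc5, an inhibitor of apoptosis active in mitosis (adjusted p = 5.66e-05), 2.30 ± 0.41 for Kpna2 (7.37e-05), 1.86 ± 0.36 for the proliferation marker Mki67 (0.000499) and 1.95 ± 0.43 for Ube2c (0.00735). As given above, the excess of microglia-like cells in the cluster marked by Top2a and Ube2c was in EAE ROS+ replicate 1. Without that library the differences of Birc5, Mki67 and Ube2c were 2.30, 1.28 and 1.44, and their calls ended. S100a8 (2.50 ± 0.44, adjusted p = 5.66e-05), Fosb (1.27 ± 0.30, adjusted p = 0.0155) and the activation marker Cd69 (1.62 ± 0.34, adjusted p = 0.0039) also differed. Lag3 (2.09 ± 0.39, adjusted p = 0.000138), Siglech (1.40 ± 0.35, adjusted p = 0.0434) and Cst7 (1.17 ± 0.30, adjusted p = 0.045) differed through negative values in monocyte/macrophage-like cells, at -2.77, -2.05 and -1.31, against -0.45, -0.44 and 0.09 in microglia-like cells. In all, 19 genes of 11526 were higher and 1, Mtif2, was lower; Kpna2, Cd69 and Mtif2 fall outside the naming rule and were chosen after their values were seen. Cybb was at 0.41 ± 0.30 (adjusted p = 0.887) and Ncf1 at -0.25 ± 0.30 (adjusted p = 0.961).

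Of 17 cell cycle genes, 3 had such a class-dependent difference, with 12 adjusted over the list alone and a median of 1.07 (adjusted p = 9.1e-18; adjusted p = 0.893 with an estimated correlation). Dissociation stress genes had a median of 0.58 with 1 called and 6 adjusted over the list alone (adjusted p = 2.61e-13; adjusted p = 0.248 with an estimated correlation). Lysosome genes had a median of -0.61 (adjusted p = 9.63e-06) and interferon response genes one of -0.49 (adjusted p = 0.00149), both with adjusted p = 0.921 with an estimated correlation. The other lists had adjusted p from 0.291 to 0.998. Among these, coagulation, class II, inflammatory, chemokine, homeostatic, glycolysis and oxidative phosphorylation lists had medians, means or tests of different sign. Adjusted over the list alone, differences were positive for 3 inflammatory and 2 homeostatic genes and for 1 gene each of the glutathione, coagulation, chemokine and disease-associated lists. They were negative for 3 disease-associated genes, 2 chemokines and 1 gene each of the inflammatory, lysosome and complement lists. None of the 10 genes named by rule kept its call under every alternative. The difference of Siglech was 0.558 (adjusted p = 1) without EAE ROS- replicate 1, 2.04 without EAE ROS+ replicate 1 and 1.99 without EAE ROS- replicate 2. That of Lag3 was 1.501 (adjusted p = 0.748) without EAE ROS- replicate 1, and that of S100a8 1.88 (adjusted p = 0.481) without EAE ROS+ replicate 2. DESeq2 called 1 gene, and there were 4, 3, 10 and 4 calls without EAE ROS- replicate 1, EAE ROS+ replicate 1, EAE ROS- replicate 2 and EAE ROS+ replicate 2.

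Between EAE ROS- and healthy ROS- cells, which share a gate, 2715 of 13631 genes rose and 1914 fell. The interferon-induced chemokine Cxcl9 rose 349-fold (log2 8.45 ± 0.36, adjusted p = 6.99e-06), Cybb 84.4-fold (6.40 ± 0.32, adjusted p = 9.65e-06) and the complement component C3 263-fold (8.04 ± 0.40, adjusted p = 9.65e-06). Cybb was at 631 and 721 CPM against 7.03 and 10.2. The class II chaperone Cd74 rose 232-fold (7.86 ± 0.46, adjusted p = 1.08e-05), F10 340-fold (8.41 ± 0.61, adjusted p = 2.77e-05), Il1b 77.9-fold (6.28 ± 0.47, adjusted p = 3.18e-05) and the monocyte receptor Ccr2 95.6-fold (6.58 ± 0.51). Nos2, which makes nitric oxide, had no counts in healthy cells and was at least 227-fold higher, against a floor of 3 counts over the group; Trem1 was at least 124-fold and Hpse at least 77.6-fold higher. P2ry12 fell 15.6-fold (-3.97 ± 0.31, adjusted p = 3.45e-05), Slc2a5 14.3-fold and Tmem119 6.22-fold. Ncf1 (0.30 ± 0.20, adjusted p = 0.264) and Tnf (0.30 ± 0.24, adjusted p = 0.355) were not called. These folds compare libraries with different cell classes, since healthy libraries held no monocyte/macrophage-like cells.

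All 15 interferon response genes rose in EAE ROS- cells (15 adjusted over the list alone), with a median of 4.75 (adjusted p = 1.66e-20; adjusted p = 0.135 with an estimated correlation). All 9 class I genes rose (median 2.87, adjusted p = 9.92e-15; adjusted p = 0.128 with an estimated correlation). Of 11 class II genes 9 rose (6.26, adjusted p = 6.94e-17; adjusted p = 0.128 with an estimated correlation). Glycolysis (14 of 15 up, 2.84, adjusted p = 5.65e-14; adjusted p = 0.15 with an estimated correlation) and oxidative phosphorylation (21 of 22 up, 1.41, adjusted p = 3.71e-10; adjusted p = 0.16 with an estimated correlation) rose almost throughout. Of 7 NADPH oxidase genes 4 rose, 5 adjusted over the list alone, with Cyba at 1.76 ± 0.26 (median 1.23, adjusted p = 0.000192; adjusted p = 0.128 with an estimated correlation). ROS scavenging genes rose in 12 of 14 cases, 13 adjusted over the list alone, with Sod2 up 22.5-fold (2.29, adjusted p = 6.34e-10; adjusted p = 0.142 with an estimated correlation). Of 15 glutathione genes 9 rose and 1 fell, 11 and 1 adjusted over the list alone, with Mgst1 up 130-fold (1.23, adjusted p = 0.000101; adjusted p = 0.135 with an estimated correlation).

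Coagulation genes rose in 9 of 13 cases, with 1 lower (9 and 2 adjusted over the list alone; median 3.49, adjusted p = 8.33e-07; adjusted p = 0.15 with an estimated correlation). Inflammatory genes rose in 6 of 12 cases, Arg1 by 305-fold, with a median of 3.77, or 3.14 with genes absent from healthy cells at their bound (adjusted p = 4.15e-06; adjusted p = 0.159 with an estimated correlation). Of 13 chemokines 9 rose and 1 fell, with a median of 4.00, or 2.79 with bounds (adjusted p = 1.84e-08; adjusted p = 0.128 with an estimated correlation). Disease-associated genes rose in 9 of 16 cases and fell in 1 (3.33, adjusted p = 1.27e-08; adjusted p = 0.135 with an estimated correlation), with Apoe up 9.11-fold and Spp1 15.5-fold. Complement genes rose in 4 of 10 cases and fell in 1 (0.26, adjusted p = 0.000361; adjusted p = 0.135 with an estimated correlation). Cell cycle genes rose in 15 of 17 cases, Mki67 by 8.20-fold (2.05, adjusted p = 3.73e-07; adjusted p = 0.182 with an estimated correlation). All 15 homeostatic genes fell (-2.46, adjusted p = 1.79e-16; adjusted p = 0.135 with an estimated correlation). Lysosome genes rose in 6 of 13 cases (0.52, adjusted p = 0.109), and dissociation stress genes rose in 4 and fell in 6 of 18 (-0.51, adjusted p = 0.0994). Adjusted over the list alone, 10 disease-associated genes rose, 5 dissociation stress genes rose and 7 fell, and counts not given here were those over all genes.

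Cldn5, a tight junction gene of endothelial cells, was at 4.63 and 299 CPM in the healthy libraries, so its fall (-9.45 ± 1.93, adjusted p = 0.00545) rests mostly on healthy replicate 2, without which it was -4.50. Without EAE ROS- replicate 2 the log2 values of F10 and Arg1 were 7.64 and 7.16, against 8.41 and 8.25, and the fold of Nos2 was over 2 times smaller; Arg1 was at 8.88 without EAE ROS- replicate 1. Mgst1 and Spp1 were at 5.71 and 3.26 without healthy replicate 1 and at 7.80 and 4.71 without healthy replicate 2, against 7.02 and 3.96. Ccr2 and Arg1 had no counts in healthy replicate 2, so their folds rest on 14 and 34 counts in replicate 1. The 4629 calls became 2906 without EAE ROS- replicate 2 and 2364 without healthy replicate 1, where Ncf4 and Ctsb were no longer called (adjusted p = 0.0941 and 0.0863).

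Microglia-like cells of EAE ROS- and healthy libraries were also compared alone, and 1296 of 8073 genes rose and 970 fell in EAE. Ifitm3, an antiviral membrane protein, rose 38.8-fold (5.28 ± 0.29, adjusted p = 5.64e-10), the scavenger receptor Cd36 292-fold (8.19 ± 0.48, adjusted p = 9.31e-10), Cd74 112-fold (6.80 ± 0.41, adjusted p = 9.97e-10) and H2-Ab1 84.3-fold (6.40 ± 0.43, adjusted p = 3.19e-09). Il18bp, which binds interleukin 18, had 729 counts against 1, a ratio of 733 (131 to 28985), and C4b 550 against 2, a ratio of 276 (76.2 to 2288). The B cell chemokine Cxcl13 was at least 241-fold higher. Cybb rose 31.2-fold (4.96 ± 0.50, adjusted p = 4.2e-07), at 330 and 154 CPM against 8.51 and 0. Il1b rose 8.34-fold (3.06 ± 0.26, adjusted p = 7.05e-08), Apoe 4.67-fold (2.22 ± 0.35, adjusted p = 8.35e-05) and Spp1 30.4-fold (4.93 ± 0.56, adjusted p = 1.92e-06). Only EAE libraries held monocyte/macrophage-like cells. The relative level of their markers was 0.0049 and 0.0063 in the main healthy clusters and 0.0371 in the largest EAE one. Summed CPM of these markers over plain totals was 2064 and 2143 in EAE ROS- microglia-like cells, against 22804 and 25010 in monocyte/macrophage-like cells. For genes that class holds at higher levels, such as Il1b, its free RNA cannot be told apart from a change within microglia-like cells. P2ry12 fell 5.52-fold, from 2331 and 2461 to 436 and 432 CPM (-2.46 ± 0.23, adjusted p = 1.56e-07), and Tmem119 2.24-fold (-1.16 ± 0.23, adjusted p = 0.000815). Il6 fell (-1.91 ± 0.51, adjusted p = 0.00943), while Tnf (0.43 ± 0.31) and Ncf1 (0.08 ± 0.24) were not called.

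All 15 interferon response genes rose in microglia-like cells (median 4.18, adjusted p = 4.44e-24; adjusted p = 0.129 with an estimated correlation), as did all 9 class I genes (2.39, adjusted p = 9.12e-13; adjusted p = 0.125 with an estimated correlation). Class II genes rose in 8 of 9 cases, 9 adjusted over the list alone (4.19, adjusted p = 1.11e-11; adjusted p = 0.141 with an estimated correlation). Cell cycle genes rose in 16 of 17 cases, 17 adjusted over the list alone, Ube2c by 51.7-fold (3.21, adjusted p = 9.12e-13; adjusted p = 0.176 with an estimated correlation). Disease-associated genes, with Cst7 up 47.9-fold, Clec7a 9.88-fold and Axl 13.5-fold, rose in 11 of 15 cases and fell in 1 (2.36, adjusted p = 6.42e-09; adjusted p = 0.195 with an estimated correlation). Glycolysis genes such as Gapdh (4.36-fold) rose in 12 of 14 cases (1.45, adjusted p = 4.65e-08; adjusted p = 0.125 with an estimated correlation). Oxidative phosphorylation genes rose in 19 of 22 (0.98, adjusted p = 4.48e-09; adjusted p = 0.141 with an estimated correlation). Homeostatic genes fell in 13 of 15 cases, among them Gpr34 (-3.22 ± 0.34) and Cst3 (-2.48 ± 0.25; median -1.37, adjusted p = 9.92e-11; adjusted p = 0.125 with an estimated correlation). Dissociation stress genes fell in 14 and rose in 1 of 17, with Jun at -2.36 ± 0.24 and Fos at -1.72 ± 0.23 (median -1.68, adjusted p = 1.61e-08; adjusted p = 0.141 with an estimated correlation).

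ROS scavenging genes, Txn1 and Prdx5 among them, rose in 9 of 13 cases, 11 adjusted over the list alone (1.26, adjusted p = 3.03e-07; adjusted p = 0.125 with an estimated correlation). NADPH oxidase genes rose in 3 of 7, namely Cybb, Rac2 (1.49 ± 0.25) and Cyba (2.02-fold; median 0.21, adjusted p = 0.0212; adjusted p = 0.27 with an estimated correlation). Glutathione genes rose in 6 and fell in 1 of 12 (0.57, adjusted p = 0.0208; adjusted p = 0.237 with an estimated correlation), with Gpx3 at least 33.0-fold higher. Chemokines such as Ccl7 (37.7-fold) and Cxcl10 (19.5-fold) rose in 9 and fell in 1 of 12 (2.58, adjusted p = 7.02e-08; adjusted p = 0.125 with an estimated correlation). Coagulation genes rose in 4 of 7 (1.45, adjusted p = 0.0108, and 0.212 with an estimated correlation). Inflammatory genes rose in 4 and fell in 1 of 8 (0.77, adjusted p = 0.0208, and 0.145 with an estimated correlation). F10 and Thbs1 of the coagulation list and Arg1 of the inflammatory list are also monocyte/macrophage markers. Free RNA of that class, which healthy libraries lacked, cannot be told apart from a change within microglia-like cells for them. Lysosome genes such as Grn rose in 7 of 13 (0.80, adjusted p = 0.000602; adjusted p = 0.365 with an estimated correlation). Complement genes rose in 5 and fell in 1 of 10 (0.63, adjusted p = 0.000628; adjusted p = 0.142 with an estimated correlation). Adjusted over the list alone, 12 disease-associated, 20 oxidative phosphorylation, 9 lysosome and 2 dissociation stress genes rose, 2 inflammatory genes and 2 chemokines fell, and counts not given were those over all genes. Healthy replicate 1 held 1746 of the healthy microglia-like cells against 71 in replicate 2. Without it the calls of Cxcl13, Cyba, F10, C3, Mgst1, Ccr2 and further named genes ended. Cyba was also not called without EAE ROS- replicate 1. DESeq2 did not call Il6 (adjusted p = 0.264) or Thbs1 (adjusted p = 0.413). Nor did edgeR call Thbs1 with a replicate block (adjusted p = 0.088) or at resolution 2 (adjusted p = 0.073). Without EAE ROS- replicate 1 the log2 values of Spp1, Apoe, Cybb, Cd74, Cst7, Axl and Gpr34 were 3.77, 1.48, 4.23, 6.22, 4.66, 2.80 and -3.88, all still called, against 4.93, 2.22, 4.96, 6.80, 5.58, 3.76 and -3.22. Cybb, Cd36, Ccl7, Cxcl10 and Ube2c had no counts in healthy replicate 2, so their folds rest on 41, 4, 22, 223 and 10 counts in replicate 1, and Cst7 was at 4.86 without healthy replicate 1. The fold of Cxcl13 was over 5 times smaller without EAE ROS- replicate 1 and over 1.5 times larger without EAE ROS- replicate 2. The 2266 calls became 598 without healthy replicate 1, 1316 without EAE ROS- replicate 1 and 1194 without EAE ROS- replicate 2.

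**Figure D3:**
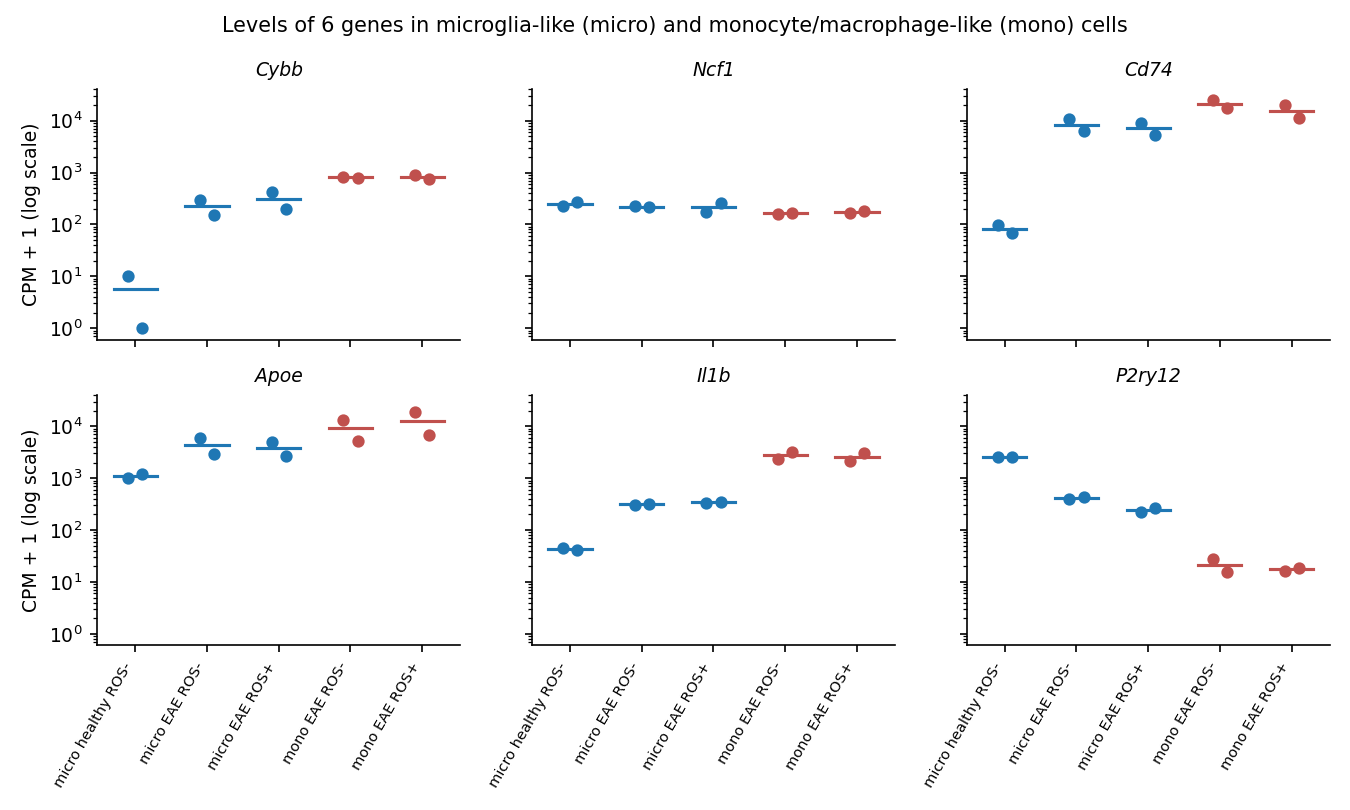
Level (CPM + 1, log axis) of 6 genes in microglia-like (blue) and monocyte/macrophage-like (red) cells; points are libraries and lines are means of 2. Cybb, Cd74, Apoe and Il1b are higher and P2ry12 lower in EAE than in healthy microglia-like cells, while Ncf1 is at 223 and 264 CPM in healthy and 221 and 216 CPM in EAE ROS- microglia-like cells.

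EAE ROS+ cells were also set against healthy ROS- cells, a comparison in which disease and gate differ together. Of 13631 genes, 3186 rose and 2921 fell. Cybb rose 122-fold (6.93 ± 0.33, adjusted p = 3.93e-06), Il1b 111-fold (6.79 ± 0.48), Cd74 236-fold (7.88 ± 0.46), F10 512-fold, Arg1 584-fold (9.19 ± 0.85), Mgst1 301-fold (8.23 ± 0.58) and Apoe 18.6-fold (4.22 ± 0.54). The neutrophil genes Camp and Ngp were at least 160-fold and at least 197-fold higher. P2ry12 fell 72.4-fold (-6.18 ± 0.34, adjusted p = 4.88e-06) and Slc2a5 109-fold (-6.77 ± 0.28, adjusted p = 2.71e-06). Ncf1 (0.36 ± 0.20, adjusted p = 0.163) and Tnf (0.13 ± 0.24, adjusted p = 0.68) were not called. Without healthy replicate 1 the 6107 calls became 3838 and Mgst1 was at 6.92, against 9.02 without healthy replicate 2; Apoe was at 3.34 without EAE ROS+ replicate 1, and the folds of Camp and Ngp were over 2 times smaller without EAE ROS+ replicate 2. Arg1 had no counts in healthy replicate 2.

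In this comparison all 15 homeostatic genes fell (median -4.51) and all 15 interferon (5.23) and 9 class I genes (2.92) rose. Medians with rises in most members were 6.39 for class II (9 of 11), 3.25 for glycolysis (14 of 15), 1.60 for oxidative phosphorylation (21 of 22), 2.75 for ROS scavenging (12 of 14), 1.81 for glutathione (11 of 15, 2 lower), 1.45 for NADPH oxidase (5 of 7) and 4.49 for coagulation (9 of 13, 2 lower). Inflammatory genes (6 of 12 up) had a median of 4.69, or 2.79 with genes absent from healthy cells at their bound, and chemokines (9 up and 3 down of 13) one of 3.62, or 1.80. Disease-associated (8 up and 3 down of 16, 2.23) and complement genes (5 up and 4 down of 10, 0.74) moved both ways. These 14 lists had camera adjusted p up to 0.00877 and from 0.137 to 0.163 with an estimated correlation. Lysosome (0.34, adjusted p = 0.475), cell cycle (0.83, adjusted p = 0.133) and dissociation stress lists (-0.08, mean 0.04, adjusted p = 0.81) were not called. Counted adjusted over the list alone, these numbers changed by at most 1 gene.

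In the mm10 build, S100a9 (ENSMUSG00000056071) lies on chromosome 3 from 90692632 to 90695721, P2ry12 (ENSMUSG00000036353) on chromosome 3 from 59216272 to 59262871 and Fscn1 (ENSMUSG00000029581) on chromosome 5 from 142960343 to 142973185. Cybb (ENSMUSG00000015340) lies on chromosome X from 9435252 to 9487771, Cd74 (ENSMUSG00000024610) on chromosome 18 from 60803848 to 60812652 and Ube2c (ENSMUSG00000001403) on chromosome 2 from 164769898 to 164778822. Values of H2-K1, H2-D1 and other class I genes, and of Ifit, Oas, Gbp, Ccl3 and Ccl4 genes, are less certain than the rest, since members of these families are alike and counting could split or drop their reads.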

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

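The tests of UMI content, of free microglial RNA and of random loading for cells with both gene sets, of microglial UMIs per cell for the endothelial cells, of free RNA in monocyte/macrophage-like cells, of pairs with a monocyte/macrophage-like cell and of free S100a8 RNA were chosen after the result was seen; the others were chosen before.

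A set of 527 cells carried both microglial and monocyte/macrophage marker genes. Cst7, Cd36, Cxcl13 and the cell cycle genes Top2a and Stmn1 were among their leading genes. They were 17.0% and 9.29% of EAE ROS- and 4.13% and 1.70% of EAE ROS+ cells, and their class entered no comparison of its own. Free microglial RNA at the level found in monocyte/macrophage-like cells is too little to explain them. Over 233 and 248 microglial genes that were neither markers nor used for clustering, summed CPM was 3.03 and 3.33 times that of monocyte/macrophage-like cells. Each set was chosen in the other EAE ROS- library. A larger share of free RNA in these cells cannot be told apart by this, since they were grouped by microglial genes and any source raises such genes together. Pairing by random loading is argued against, since it needs pairs of monocyte/macrophage-like cells, of which about 0.5 or more would be expected to reach the summed median UMIs of the 2 classes, and cells of that class with so many UMIs were at most 0.325 times as many as those pairs in any EAE library. A pair of cells in 1 droplet may still explain them: 0 genes lay over 2-fold above every other cluster in both EAE ROS- libraries, and median UMIs were 1.23 and 1.39 times the summed medians of the 2 classes. A larger share of free RNA, pairs that stayed together through sorting, uptake of material by a cell, or a cell state stay open.

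In healthy replicate 2, 131 of 202 cells carried endothelial genes beside microglial ones, against 9 of 1755 in replicate 1. Free microglial RNA in a lone endothelial cell is argued against, since these cells held 143 microglial marker UMIs each, 1.65 times the 86.6 of microglia-like cells. Free endothelial RNA cannot be told apart from endothelial cells here: marker CPM was 5.86 times that of the library's other cells (1207 against 206), but the same genes set these cells apart. A microglial and an endothelial cell in 1 droplet stays open and was not tested; the CD11b sort would remove endothelial cells that came alone. No biological explanation was tested.

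The gate difference depended on the class for 20 genes by the test of the difference itself. These were split by the class with the larger absolute ROS+ minus ROS- difference in mean log2 CPM. It lay in microglia-like cells, upward, for 13 and in monocyte/macrophage-like cells, downward, for 6. Some moved in both classes. All 13 but S100a8, Ube2s and Fosb were also lower in ROS+ monocyte/macrophage-like cells. Of the 6, Cdc20 (1.35) and Cox6a2 (0.260) were also higher in ROS+ microglia-like cells. For the 13 with the larger difference upward in microglia-like cells, free RNA from monocyte/macrophage-like cells is argued against. Their median CPM in ROS+ microglia-like cells was at least 7.81 times that of the whole library. Of the 13, Fosb (1.34 and 2.12) and Cd69 (4.109 and 1.201) had lower ratios, and S100a8 had at most 0.158, so free RNA from other cells is a possible explanation for S100a8. RNA of a monocyte/macrophage-like cell in the same droplet would by itself lower most of the set. Its median ratio of CPM in such ROS+ cells to EAE ROS- microglia-like cells was at most 0.192. The ratios were higher for S100a8 (26.6 and 42.3), Fosb (2.31 and 1.73) and Cd69 (0.695 and 1.19). This cannot decide on pairs, since clustering could keep pairs with a dividing microglia-like cell and place other pairs among mixed cells. At resolution 2, a mixed cluster led by Hist1h2ap and Top2a held 29 and 15 EAE ROS+ cells, and the microglia-like class held 22 and 20. Leaving out cells of high UMI count kept 0.943 of the median log2 difference but took only 3 of 28 and 0 of 22 ROS+ cells. Pairs therefore cannot be told apart, and a difference of cell cycle or of activation between the gates stays open. The 6 with the larger difference downward in monocyte/macrophage-like cells included Lag3, Siglech and Cst7. For these 6, a smaller amount of free microglial RNA cannot be told apart from a change within the cells. Their median was -1.59, and 12 other microglial markers ran from -1.69 (Sparc) to 0.08 (Fcrls), with a median of -0.41.

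Classes outside the comparisons held 324 dendritic cell-like cells, of which 196 and 121 were in the EAE ROS- libraries and none in healthy ones. There were 76 T cell-like cells, 37 and 35 of them in the EAE ROS- libraries, although the sort was for CD11b. Their cluster was also the highest for natural killer cell markers, so it can hold natural killer cells as well. All 22 neutrophil-like cells were in EAE ROS+ libraries.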

How the results depend on the processing

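The alternatives without the 2 clusters of mixed genes, without cells of high UMI count, and with a replicate block over the EAE libraries only were chosen after seeing the data; the others were planned.

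In all cells, calls between the EAE gates (295) were 1006 with no low count filter and 153 with only the 2 groups compared. Those between the EAE gates in microglia-like cells (6) were 30 with no low count filter, 37 with the stricter cell filter, which left EAE ROS+ replicate 2 with 17 cells and out of the fit, 1 with class by marker sums, 1 at resolution 2 and 0 with only the 2 groups compared (494 at an unadjusted p under 0.05). Monocyte/macrophage-like cells (0 calls) gave 8 with DESeq2 and 72 with no low count filter. Microglia-like cells of EAE ROS- against healthy (1296 up, 970 down) gave 965 with DESeq2 (664 up, 301 down). Class-dependent differences (20) were 1 with DESeq2, 32 with the stricter cell filter and 13 at resolution 2. Apart from the dropped library the cause was not tested.

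With a library left out, calls ran from 123 (without EAE ROS+ replicate 2) to 632 (without EAE ROS- replicate 2) between the EAE gates in all cells, from 2364 to 4295 for EAE ROS- against healthy and from 3838 to 5900 for EAE ROS+ against healthy. They ran from 0 to 26 between the EAE gates in microglia-like cells, from 598 to 2643 for EAE ROS- against healthy microglia-like cells, from 0 to 50 in monocyte/macrophage-like cells and from 3 to 10 for class-dependent differences. Each such fit leaves a group with 1 library, which is assumed to vary like the other groups, and fewer residual degrees of freedom; the cause of a change was not tested further.

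The labels give no meaning to replicate numbers. Deviations of same-numbered EAE ROS+ and ROS- libraries correlated across genes at 0.621 in all cells, 0.209 in microglia-like and 0.660 in monocyte/macrophage-like cells, and those of EAE and healthy libraries between -0.126 and 0.00516. With a replicate block, calls between the EAE gates were 596 in all cells (78 up, 518 down), 16 in microglia-like (all up) and 49 in monocyte/macrophage-like cells (21 up, 28 down), and with a replicate block over the EAE libraries only they were 1839 in all cells (651 up, 1188 down, against 17 and 278 without a block) and 74 in microglia-like cells (55 up, 19 down, against 6 and 0); the cause was not tested. Counts of the 3 comparisons against healthy cells stayed, with a block, within 1.5 times. Lists called between the EAE gates with a block were 9, 11 and 9 in all, microglia-like and monocyte/macrophage-like cells, against 9, 10 and 6.

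Gene lists called with an estimated correlation were 0 in all 7 comparisons, against 9, 15, 14, 10, 17, 6 and 4 of 17 at the preset one. The estimated form also uses only the residual degrees of freedom of the fit, 2 or 3 here. The 0 calls can therefore not be laid to the correlation between genes alone. With an average log2 CPM of at least 5, lists called in the same order of comparisons were 5, 14, 13, 8, 13, 4 and 4, of 16 lists (17 in the last). Of these, 4, 13, 13, 7, 13, 3 and 4 were also called before. Among single genes, Tnf in EAE ROS- against healthy microglia-like cells was -0.698 at resolution 0.5 (adjusted p = 0.0493), against 0.43 without a call. No other named gene changed direction with a call on either side. Named genes that kept their call under every alternative run were 11 of 25 between the EAE gates in all cells, 80 of 85 for EAE ROS- and 83 of 84 for EAE ROS+ against healthy, 68 of 83 in microglia-like cells against healthy, 0 of 4 between the EAE gates there and 0 of 10 for class-dependent differences.

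The difference in the share of microglia-like cells kept its sign throughout. It ran from -14.6 to -27.7 points between the EAE gates. For EAE ROS- against healthy it ran from -12.7 (without healthy replicate 1) to -80.9 points (resolution 0.5). At resolution 0.5 no cluster scored for endothelial markers. All 202 cells of healthy replicate 2 were thus named microglia-like, against 71 at resolution 1, so the -80.9 points rest on that naming. The fit of microglia-like cells at resolution 0.5 holds these cells as well. Resolution 0.5 was not run for the EAE gates in microglia-like cells or for class-dependent differences, since too few ROS+ cells were left in the class. The shallowest microglia-like sums were those of EAE ROS+, at 295618 and 140340 UMIs, and of healthy replicate 2, at 223232.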

Other observations

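No test of this part was chosen after a result was seen, since it reports values only. In the EAE ROS- libraries (n = 2), monocyte/macrophage-like cells held more RNA of Cybb, Il1b, Arg1, Nos2, F10 and Mgst1 than microglia-like cells. Arg1 and F10 are among the markers that named the class, so their direction was partly fixed by the naming. CPM here are over plain totals, without TMM scaling. Cybb was at 826 and 789 CPM in monocyte/macrophage-like and 294 and 151 CPM in microglia-like cells, and Il1b at 2390 and 3265 against 300.2 and 323 CPM. Arg1, which breaks down arginine, was at 1130 and 2317 against 47.9 and 105 CPM, and Nos2 at 95.6 and 244 against 3.94 and 11.5 CPM. F10 was at 422 and 684 against 24.2 and 49.1 CPM, and Mgst1 at 331 and 427 against 14.2 and 24.6 CPM. The oxidase gene Ncf1 ran the other way, at 161 and 166 CPM in monocyte/macrophage-like and 221 and 216 CPM in microglia-like cells. Tnf was at 91.5 and 89.8 against 196 and 194 CPM, and Ccl12 at 83.1 and 34.0 against 1481 and 2066 CPM.

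Complement genes were divided between the classes. C1qa was at 13112 and 10383 CPM in microglia-like and 2004 and 680.4 CPM in monocyte/macrophage-like cells. C4b was at 109 and 145 against 19.2 and 15.7 CPM. Cfb was higher in monocyte/macrophage-like cells, at 650.0 and 1198 against 88.1 and 147 CPM, as was C3 at 199 and 201 against 22.7 and 24.6 CPM. Cd74 stood at 28242 and 25268 CPM in dendritic cell-like, 24659 and 17533 in monocyte/macrophage-like and 10620 and 6205 in microglia-like cells. These differences between classes were not tested, and free RNA adds to the lower values of each pair.

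Microglia-like cells of healthy and EAE libraries lay mostly in different clusters. Clusters marked by Gpr34 and P2ry12, or by Klf2 and Jun, held 72.9% and 26.5% of microglia-like cells of healthy replicate 1. In healthy replicate 2 they held 67.6% and 19.7%, and they held none of those from EAE. A small cluster led by Cox6a2 was shared. It held 0.229% and 11.3% of microglia-like cells of healthy replicates 1 and 2, against 4.27% and 5.76% in EAE ROS- and 7.14% and 22.7% in EAE ROS+. A cluster marked by Cst7, Cd36 and Cxcl13 held 62.0% and 59.3% of EAE ROS- microglia-like cells, against 5 of 28 and 3 of 22 in EAE ROS+. A cluster marked by Top2a and Ube2c held 18.4% and 26.3% of EAE ROS- microglia-like cells, against 18 of 28 and 6 of 22 in EAE ROS+. A cluster marked by Ccl3, Ccl4 and Tnf held 15.4% and 8.64% of them, against 3 of 28 and 8 of 22.

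Monocyte/macrophage-like cells fell into 9 clusters, of which 5 were picked here after their counts were seen; replicates 1 and 2 differed in their shares in both EAE gates, and no difference between shares was tested. Cells of a cluster marked by Nos2 and Inhba, a subunit of activin, numbered 86 and 401 of the 638 and 988 such cells in EAE ROS- libraries, and 74 and 528 of 1630 and 2154 in EAE ROS+. Cells of a cluster marked by Apoe, Gpnmb and Ms4a7 numbered 151 and 25 in EAE ROS- and 469 and 67 in EAE ROS+ libraries. An interferon cluster marked by Rsad2 and Ifit1 held 6 and 57 EAE ROS- cells and 29 and 233 EAE ROS+ cells. A cluster marked by Ccr2, H2-Eb1 and H2-Aa held 246 and 135 EAE ROS- cells against 324 and 110 EAE ROS+ cells. A cluster marked by Saa3 and Cxcl1 held 67 and 37 EAE ROS- cells and 469 and 85 EAE ROS+ cells.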
